A study of Mus musculus with 18 samples.

How the data were processed

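RNA from the ankle joint, dorsal root ganglia (DRG) and spinal cord of C57BL/6 mice aged 10 weeks was sequenced in bulk, 8 h after 100 µl of monosodium urate (MSU) crystals or phosphate-buffered saline (PBS) was injected into the right ankle joint. The labels call the control animals untreated, while the treatment protocol, the design summary and the column names say that they received PBS, and they are taken here as PBS-injected. RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit for MGI sequencers, per the labels.

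The deposited tables hold the raw read count per Ensembl gene, 1 table per tissue and 1 column per library, which the authors did not normalize. Whole numbers with a different total in each library were found in every column. Per the submitters' processing notes, HISAT2, HTSeq 0.11.3, DESeq2 and the mm39 genome build were used; the notes give no role or order for them, and no annotation release or strand setting. Each table lists 55359 genes. Gene names and gene lengths and GC contents were taken from an older annotation (GENCODE M21), so a gene name may differ from the one in use for mm39, and no coordinates are given. Overlapping genes may have lost counts: the metallothionein gene Mt2 had almost no counts in any library.

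The 18 libraries formed 6 groups of 3, control and MSU in each tissue, and each tissue was compared in its own model. The labels do not state that each library came from its own animal, so p-values measure the spread between samples. Pairs of libraries within a group differed by far more than counting error (chi-square per degree of freedom of 5.69 or more), so no library was a copy of another.

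The tests, the settings, the 33 gene lists, the rule for naming genes and all alternatives but those listed below as added were chosen before the data were examined. Genes were kept by filterByExpr (minimum count of 10 and minimum total count of 15), which left 17690 genes in the ankle, 17008 in the DRG and 17507 in the spinal cord. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion (R 4.3.3), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Every adjusted p of a gene in the text is from this edgeR test unless another tool is named. CPM are counts scaled to the effective library size under TMM, given as mean ± SD of 3 libraries, and the SE of a log2 fold change is its size over the square root of F. A difference in response between 2 tissues was tested in edgeR as an interaction over all 18 libraries and 20757 genes. Overlaps of calls were tested with Fisher's exact test among genes tested in both tissues.

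The 33 gene lists were tested in each tissue with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over the lists within a tissue. The same test with a correlation estimated from the data is given beside each. Counts of members use the adjustment over all genes, then the adjustment over the list alone.

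The genes named in the text follow a rule. Per tissue they are the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, with a mean of at least 1 CPM and no predicted gene models. To these were added 23 genes fixed in advance, up to 4 members of each list with the smallest p-values, the 5 largest differences each way for each interaction, and the 10 genes called in all 3 tissues with the smallest p-values. Genes named outside this rule are said to be so. A gene with no counts in a group is given as a lower bound against 3 counts over that group, and one with 1 to 3 counts as a ratio with a 95% binomial interval. Folds on slightly more control counts depend on the prior count of edgeR and can differ from the ratio of the CPM means. Examples are Csf3 with 6 counts in the ankle and 6 in the DRG controls, and Cxcl1 with 4 and Selp with 5 in the spinal cord controls.

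The alternatives were RLE and upper quartile size factors, no count filter and a filter on a mean count of 10, DESeq2 1.42.0, limma-voom, leaving out each library, a block on the replicate number, a test against a 1.5-fold change, a fit of all 18 libraries, a log2 fold change of at least 1, and for overlaps a threshold of 0.01. For the lists they were an estimated correlation, the block, and fry. Added after the data were seen were a correction for each library's trends with GC content and gene length, list counts under other settings, and list tests of differences between tissues.

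The tests were also run on simulated data, drawn from negative binomial distributions with each tissue's own mean levels, dispersions and library sizes, with 200 genes changed 1.5-, 2- or 4-fold in 3 against 3 libraries. edgeR recovered 7.46, 55.2 and 78.8% of these in the ankle, 44.8, 62.7 and 93.9% in the DRG, and 49.3, 79.1 and 92.4% in the spinal cord. Of its calls, 13.0% (14 of 108), 10.7% (16 of 150) and 11.4% (19 of 166) were false, above the nominal 5%, and the counts of called genes should be read with a possible excess in mind. Its size does not carry over to them, because the share of false calls depends on how many genes change. Only 200 genes changed here, while the real comparisons called 43.3, 35.4 and 9.66% of the tested genes. The false share in the simulation was 26.2, 18.8 and 14.4% for DESeq2 and 12.3, 10.8 and 12.5% for limma-voom. For interactions it was 9.46% (7 of 74) between ankle and DRG and 2.90% (2 of 69) between ankle and spinal cord. camera found the changed list in each tissue and called 0, 0 and 1 of 32 unchanged lists. Genes were drawn independently of each other, so these runs do not test the fixed correlation of 0.01. In the real data the estimated correlation varied widely, with -0.07 for neutrophil chemoattractants and receptors and 0.97 for skeletal muscle markers in the DRG.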

Results

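RNA was sequenced from 3 tissues of mice 8 h after 100 µl was injected into the right ankle joint. The injection held either monosodium urate (MSU) crystals, the crystals that deposit in gouty joints, or phosphate-buffered saline (PBS) as the control. The tissues were the ankle joint, the dorsal root ganglia (DRG), which hold the cell bodies of sensory neurons, and the spinal cord. Each tissue gave 3 control and 3 MSU libraries, 18 libraries in 6 groups. The total count per library, to 5 digits, was 38813000, 24088000 and 13819000 in ankle controls 1 to 3 and 25215000, 13826000 and 11633000 in ankle MSU libraries 1 to 3. In the DRG it was 36014000, 22491000 and 17638000 in the controls and 15348000, 20417000 and 27518000 in the MSU libraries. In the spinal cord it was 20499000, 13527000 and 13690000 in the controls and 20535000, 19926000 and 23673000 in the MSU libraries. A count of 3 equalled 0.0773 to 0.258 counts scaled to library size (CPM) across the libraries, and intervals and floors given here cover counting error only.

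In the ankle joint, the comparison asks which genes respond where the crystals were placed. Transcripts of cytokines, neutrophil chemoattractants and interleukin-1 signalling rose. Csf3 (ENSMUSG00000038067), the growth factor that drives neutrophil production, rose 2703-fold, from 0.0585 ± 0.0515 CPM in controls to 213 ± 75.6 CPM with MSU (mean ± SD, n = 3, log2 fold change 11.40, SE 0.50, edgeR adjusted p = 2.75e-05). The controls held 6 Csf3 counts in total, so this fold depends on the prior count. Il6 (ENSMUSG00000025746), a cytokine that induces the acute phase response, rose 935-fold, from 0.389 ± 0.0997 to 391 ± 145 CPM (log2 fold change 9.87, SE 0.40, adjusted p = 1.49e-05). Il1b (ENSMUSG00000027398), the cytokine released through the inflammasome that MSU crystals activate, rose 78.6-fold, from 10.8 ± 0.871 to 850 ± 530 CPM (log2 fold change 6.30, SE 0.68, adjusted p = 0.00209). Nlrp3 (ENSMUSG00000032691), the sensor of that inflammasome, rose 39.3-fold, from 4.09 ± 0.984 to 165 ± 87.5 CPM (log2 fold change 5.30, SE 0.63, adjusted p = 0.003). For each of these 4 genes, all 3 MSU libraries lay above all 3 controls.

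The inflammatory gene lists moved with them. Of 12 tested neutrophil chemoattractants and receptors, 11 rose (11 when adjusted over the list alone, camera adjusted p = 6.26e-08, but adjusted p = 0.366 with an estimated correlation). Among these, Cxcl2 rose 819-fold (log2 fold change 9.68, SE 0.75), Cxcl1 146-fold (7.19, SE 0.50) and Cxcl5 91.5-fold (6.52), while Ppbp, a platelet chemokine gene named after its value was seen, had a log2 fold change of 0.87 (adjusted p = 0.470). All 25 tested cytokines and NF-kB targets rose (25 when adjusted over the list alone, camera adjusted p = 5.12e-14, adjusted p = 0.366 with an estimated correlation). They included Tnf at 5.41-fold, the leukaemia inhibitory factor gene Lif at 41.6-fold and the leukocyte adhesion gene Icam1 at a log2 fold change of 2.45. Of 16 tested interleukin-1 and inflammasome genes, 12 rose and 2 fell (13 and 2 when adjusted over the list alone, camera adjusted p = 5.07e-05, adjusted p = 0.366 with an estimated correlation). Il1rn, the antagonist of the interleukin-1 receptor, rose 19.3-fold, and the falls were Il18 (log2 fold change -0.41) and Pycard (-0.94), the inflammasome adaptor, both named after their values were seen. The count of falls was 1 without ankle control 1, ankle control 2, ankle MSU 1 or ankle MSU 3. All 24 tested interferon response genes rose (24 when adjusted over the list alone, camera adjusted p = 1.36e-11, adjusted p = 0.366 with an estimated correlation). Ifi44 rose 10.2-fold, the antiviral gene Mx2 5.75-fold and the interferon signalling factor Stat2 2.65-fold.

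Neutrophil marker transcripts were higher in the MSU joints. Of 18 mature neutrophil markers, 17 rose and 1 fell (17 and 1 when adjusted over the list alone, camera adjusted p = 3.86e-08, adjusted p = 0.366 with an estimated correlation). Clec4e, a pattern recognition receptor, rose 57.1-fold, and Csf3r, the receptor for the product of Csf3, rose 7.30-fold. Asprv1 (log2 fold change -0.81), named after its value was seen, was the fall, and it did not pass without ankle control 2, ankle control 3, ankle MSU 1 or ankle MSU 3. The alarmin gene S100a9 rose 6.57-fold, from 184 ± 152 to 1210.3 ± 346 CPM (adjusted p = 0.0354). Its adjusted p was 0.0638 without ankle control 1, 0.0795 without control 3, 0.0710 without MSU 1, 0.0941 without MSU 2, 0.104 without MSU 3 and 0.0837 with no count filter (6.96e-05 to 0.104 over the alternatives). Of 18 monocyte and macrophage markers, 8 rose (8 when adjusted over the list alone, camera adjusted p = 0.0220, adjusted p = 0.540 with an estimated correlation). They included the Fc receptor gene Fcgr1 at 6.11-fold and the integrin gene Itgam at 4.79-fold. Of 17 matrix proteases and inhibitors, 13 rose and 2 fell (13 and 3 when adjusted over the list alone, camera adjusted p = 0.000141, adjusted p = 0.366 with an estimated correlation). Mmp3, a collagen- and proteoglycan-degrading protease, rose 42.2-fold, from 39.8 ± 3.59 to 1679 ± 373 CPM, and Adamts4, an aggrecan-cleaving protease, rose 31.5-fold. The falls were the protease inhibitor genes Timp2 (-0.98), named after its value was seen, and Timp3 (-0.98).

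Of 19 acute phase and glial reactivity genes, 15 rose and 1, the cytoskeletal gene Vim, fell (log2 fold change -0.94, named after its value was seen). When adjusted over the list alone 16 rose and 1 fell, with camera adjusted p = 1.61e-07 and adjusted p = 0.366 with an estimated correlation. Saa3, a serum amyloid gene, rose from 2.89 ± 1.99 to 2640.2 ± 480.4 CPM. Of 19 hypoxia and glycolysis genes, 13 rose and 3 fell (13 and 3 when adjusted over the list alone, camera adjusted p = 0.000903, adjusted p = 0.366 with an estimated correlation). Hif1a, the hypoxia-inducible transcription factor, rose 5.28-fold and Pfkfb3, a driver of glycolysis, 7.65-fold. The falls, Car9 (-1.0), Egln3 (-0.36) and Pdk1 (-0.58), were named after their values were seen, and 1 passed without ankle control 3 or without ankle MSU 3. Of 16 prostaglandin and leukotriene genes, 7 rose and 3 fell (7 and 3 when adjusted over the list alone, camera adjusted p = 0.277, adjusted p = 0.540 with an estimated correlation). The list's median was -0.05, its mean 0.59 and its test direction upward. Ptgs2, the inducible cyclooxygenase, rose 60.3-fold (log2 fold change 5.91, SE 0.73, adjusted p = 0.00363), and the falls were Alox5 (-0.51), Ltc4s (-1.14) and Ptgs1 (-1.0), the first pair named after their values were seen.

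Keratinocyte, adipocyte, muscle and myelin transcripts fell in the MSU joints. Inmt, which encodes an indole-methylating enzyme, fell by 5.07 on the log2 scale (SE 0.25, adjusted p = 9.03e-06), from 85.7 ± 7.47 to 2.44 ± 0.966 CPM. Cyp2e1, which encodes a cytochrome P450, fell by 4.71 (SE 0.24, adjusted p = 5.77e-06), from 36.9 ± 7.4 to 1.45 ± 0.388 CPM. Of 13 keratinocyte markers 11 fell (11 when adjusted over the list alone, camera adjusted p = 0.000559, adjusted p = 0.408 with an estimated correlation), including Flg2 (-2.05) and Dsg1a (-1.77), structural genes of the epidermis. Of 12 adipocyte markers 8 fell (9 when adjusted over the list alone, camera adjusted p = 0.00144, adjusted p = 0.366 with an estimated correlation), including Pck1 (-3.69), an enzyme of glyceride synthesis in fat. Of 14 skeletal muscle markers 7 fell (8 when adjusted over the list alone, camera adjusted p = 0.0180, adjusted p = 0.540 with an estimated correlation), and 4 fell without ankle control 1 or after a correction for GC content and gene length. Of 8 tested oligodendrocyte markers, which are myelin genes that Schwann cells share in part, 6 fell (6 when adjusted over the list alone, camera adjusted p = 0.00310, adjusted p = 0.366 with an estimated correlation), including Mbp (-0.71) and Aspa (-1.96). Of 14 nociceptor genes, 5 fell and 2 rose (5 and 2 when adjusted over the list alone, camera adjusted p = 0.380, adjusted p = 0.578 with an estimated correlation). Trpv1, the capsaicin and heat receptor, fell by 1.72 and Piezo2, the touch receptor, by 2.18. The genes of the neuropeptides CGRP and substance P rose, Calca 9.33-fold, from 0.317 ± 0.164 to 3.36 ± 2.09 CPM, and Tac1 5.08-fold. Their counts in control and MSU joints were low, at 30 and 134 for Calca and 27 and 85 for Tac1. The nociceptor sodium channel gene Scn10a had 3 and 4 counts, and which cells held the Calca and Tac1 transcripts was not tested.

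Of 16 glucocorticoid-induced genes, 8 rose and 1 fell in the ankle (10 and 1 when adjusted over the list alone, camera adjusted p = 0.00317, adjusted p = 0.578 with an estimated correlation). The count of rises was 13 without ankle control 2, and 4 without ankle control 3, ankle MSU 2 or ankle MSU 3. Ankle control 2 stood apart from the other controls in these genes. Its Fkbp5 level, a steroid receptor co-chaperone, was 191 CPM against 55.6 and 52.1, and the Fkbp5 log2 fold change of 1.65 (adjusted p = 0.0941) was 2.53 without that library (adjusted p = 6.14e-06). Metallothionein Mt1 rose 15.9-fold, and the fall was Plin4 (-1.13), a lipid droplet gene.

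The edgeR quasi-likelihood test called 3823 ankle genes higher and 3833 lower with MSU of 17690 tested, of which 1504 and 1808 changed at least 2-fold. The groups of 3 did not overlap for 55.9% of the tested genes, against 10% by chance. Upper quartile normalization and a fit of all 18 libraries moved the ankle median log2 fold change from -0.02 to -0.12 and -0.13, and the share of rises among the calls from 49.9% to 40.6% and 39.0%.

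**Figure D1:**
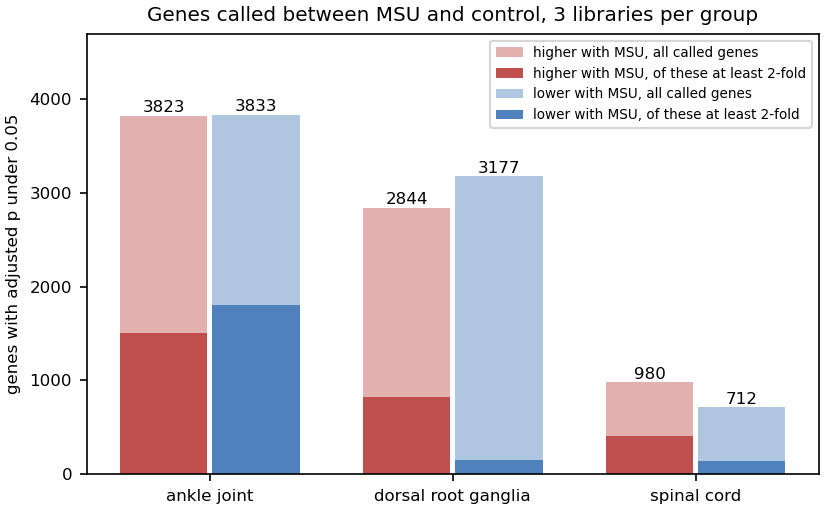
Number of genes higher and lower with MSU in each tissue at an adjusted p under 0.05, with 3 libraries per group and the darker part of each bar showing changes of at least 2-fold. In the ankle joint 3823 genes were higher and 3833 lower.

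In the DRG, the comparison asks how the ganglia respond to crystals in the joint. Acute phase, cytokine, chemokine and glucocorticoid-induced transcripts rose, and several transcripts of sensory neurons fell. Csf3 rose 278-fold, from 0.0722 ± 0.0672 to 23.5 ± 1.97 CPM (n = 3, log2 fold change 8.12, SE 0.29, edgeR adjusted p = 1.85e-07). Sele (ENSMUSG00000026582), which encodes the E-selectin by which activated endothelium captures leukocytes, rose 137-fold (log2 fold change 7.09, SE 0.24, adjusted p = 1.79e-07). Sgk1 (ENSMUSG00000019970), a kinase gene induced by glucocorticoids, rose 5.46-fold, from 30.3 ± 3.37 to 165 ± 13.0 CPM (log2 fold change 2.45, SE 0.10, adjusted p = 3.39e-07). Nefm (ENSMUSG00000022054), which encodes a neurofilament of large axons, fell by 1.02 on the log2 scale, from 4754 ± 369 to 2339 ± 355 CPM (SE 0.12, adjusted p = 0.00026). In each of these 4 genes the 3 MSU libraries lay on the same side of all 3 controls.

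All 16 glucocorticoid-induced genes rose in the DRG (16 when adjusted over the list alone, camera adjusted p = 1.08e-13, adjusted p = 0.206 with an estimated correlation). Fkbp5 rose 2.56-fold, from 56.0 ± 7.44 to 143 ± 10.3 CPM, and the kinase gene Map3k6 8.59-fold. Of 22 tested cytokines and NF-kB targets, 20 rose (21 when adjusted over the list alone, camera adjusted p = 2.78e-10, adjusted p = 0.0585 with an estimated correlation). Selp, the P-selectin gene, rose 65.7-fold and Nfkbia, the NF-kB inhibitor, 4.18-fold. Of 10 neutrophil chemoattractants and receptors, 8 rose (8 when adjusted over the list alone, camera adjusted p = 0.000136, adjusted p = 0.162 with an estimated correlation), led by Csf3 and by Cxcl1 at 111-fold. Of 18 acute phase and glial reactivity genes, 14 rose (15 when adjusted over the list alone, camera adjusted p = 8.07e-08, adjusted p = 0.162 with an estimated correlation). Saa3 rose 341-fold, the iron-binding lipocalin Lcn2 8.11-fold, and Gfap, the intermediate filament of reactive glia, 9.33-fold. Saa1 had 3604 counts with MSU and 3 in the controls, a ratio of 1402 (95% counting interval 479 to 6800). Tnfsf11, the gene of the bone-resorption ligand RANKL, had no counts in the controls and was at least 55.6-fold higher with MSU, against a floor of 3 counts over the control group.

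Of 19 immediate early genes, 14 rose (15 when adjusted over the list alone, camera adjusted p = 8.07e-08, adjusted p = 0.206 with an estimated correlation). The activity marker Fos rose 4.79-fold and Nr4a1 3.12-fold. Of 15 interleukin-1 and inflammasome genes, 10 rose (12 when adjusted over the list alone, camera adjusted p = 1.80e-06, adjusted p = 0.188 with an estimated correlation). Il1b rose 5.29-fold, from 0.858 ± 0.208 to 4.54 ± 0.683 CPM, and the interleukin-1 receptor gene Il1r1 3.20-fold. Nlrp3 rose 2.46-fold, but its adjusted p was 0.120 in the fit of all 18 libraries (0.00302 to 0.120 over the alternatives). Of 17 mature neutrophil markers, 11 rose (11 when adjusted over the list alone, camera adjusted p = 2.51e-05, adjusted p = 0.412 with an estimated correlation). The C-type lectin gene Clec4d rose 12.8-fold, while S100a8 had a log2 fold change of 1.43 (adjusted p = 0.130) and S100a9 of 1.27 (adjusted p = 0.122), and DESeq2 gave adjusted p values of 0.0333 and 0.0304 for this pair (0.000263 to 0.654 and 0.00336 to 0.662 over the alternatives). Of 16 monocyte and macrophage markers, 10 rose, or 6 without DRG MSU 3 (11 when adjusted over the list alone, camera adjusted p = 0.000136, adjusted p = 0.401 with an estimated correlation), including the lipopolysaccharide receptor gene Cd14 at 8.17-fold. Of 24 interferon response genes, 11 rose (11 when adjusted over the list alone, camera adjusted p = 0.000134, adjusted p = 0.546 with an estimated correlation), or 17 without DRG MSU 1 and 6 without DRG MSU 2 or MSU 3. Ptgs2 rose 14.8-fold, from 0.489 ± 0.159 to 7.34 ± 1.05 CPM (log2 fold change 3.89, SE 0.26, adjusted p = 7.95e-06).

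Of 15 sensory neuron markers, 10 fell in the DRG (12 and 1 when adjusted over the list alone, camera adjusted p = 0.000308, adjusted p = 0.520 with an estimated correlation). The count of falls was 6 without DRG control 1 or without DRG MSU 2, and 1 marker rose without DRG MSU 1. Besides Nefm, the neurofilament gene Nefh fell by 0.63 and the neuronal splicing factor gene Rbfox3 by 0.71. Of 27 nociceptor genes, 10 fell (10 when adjusted over the list alone, camera adjusted p = 0.0229, adjusted p = 0.604 with an estimated correlation). Without DRG control 3 there were 5 rises, and without DRG MSU 1 there was 1. Piezo2 fell by 0.63 and Asic1, an acid-sensing channel gene, by 0.78. Scn10a, the nociceptor sodium channel, fell by 0.54, from 1458 ± 244 to 1005 ± 78.9 CPM, with an adjusted p of 0.00692 that became 0.582 in the fit of all 18 libraries (3.56e-08 to 1 over the alternatives). That fit uses 1 dispersion per gene for the 3 tissues, and Scn10a varied widely in the spinal cord. It stood at 4.35 CPM in spinal cord control 3 and 8.43 CPM in MSU 3, against 0 to 0.355 CPM in the other cord libraries. Trpv1 had a log2 fold change of -0.06 (adjusted p = 0.562) and Trpa1, the irritant receptor, of 0.01 (adjusted p = 0.940). Calca had a log2 fold change of 0.21 (adjusted p = 0.320), and 0.42 without DRG control 3 (adjusted p = 0.0160). Tac1 had a log2 fold change of 0.30 (adjusted p = 0.0794), which was 0.40 without DRG control 3 (adjusted p = 0.0295) and 0.41 without DRG MSU 1 (adjusted p = 0.00357). Atf3, a marker of injured sensory neurons, had a log2 fold change of 0.36 (adjusted p = 0.510), and 0.86 without DRG control 3 (adjusted p = 0.00202).

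Glial and vessel transcripts also changed in the ganglia. Of 12 Schwann and satellite glia markers, 5 rose and 2 fell (5 and 2 when adjusted over the list alone, camera adjusted p = 0.272, adjusted p = 0.604 with an estimated correlation). Glul, the glutamine synthetase gene of satellite glia, rose 2.10-fold, while Fabp7, a fatty acid binding protein gene of satellite glia, fell by 2.06, from 210 ± 5.29 to 50.3 ± 8.03 CPM (SE 0.11, adjusted p = 1.89e-06). Kcnj10, their potassium channel gene, fell by 0.98. Of 12 endothelial markers, 5 fell and 3 rose (5 and 3 when adjusted over the list alone, camera adjusted p = 0.272, adjusted p = 0.604 with an estimated correlation). The tight junction gene Cldn5 fell by 1.67 and Ly6c1 rose 3.07-fold.

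Summed muscle and erythroid markers were higher in all 3 MSU ganglion libraries than in all 3 controls. The sum of 14 skeletal muscle markers was 409, 259.8 and 90.2 CPM in DRG controls 1 to 3 and 18789, 2174 and 2138 CPM in DRG MSU 1 to 3, and that of the erythroid markers 253, 195 and 268 against 651, 485 and 416 CPM. The muscle actin gene Acta1, named after its values were seen, stood at 2578 CPM in DRG MSU 1 and at 281 and 264 CPM in the other MSU libraries. Of the 14 muscle markers 2 rose, Myl1 and Mylpf, or 6 without DRG MSU 1, and each call was lost without any 1 of DRG controls 1 to 3, DRG MSU 2 or DRG MSU 3 (13 when adjusted over the list alone, camera adjusted p = 2.51e-05, adjusted p = 0.535 with an estimated correlation). Of 11 erythroid markers 8 rose (8 when adjusted over the list alone, camera adjusted p = 0.000372, adjusted p = 0.486 with an estimated correlation), and the number was 4 without DRG control 1, DRG control 2 or DRG MSU 2, 5 without DRG MSU 3, and 2 after a correction for GC content and gene length. The share of mitochondrial counts was 4.40 to 5.85% in the DRG MSU libraries and 2.56 to 2.94% in the DRG controls.

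The test called 2844 DRG genes higher and 3177 lower with MSU of 17008 tested, of which 827 and 147 changed at least 2-fold, and the groups did not overlap for 50.3% of genes. Fold changes fell with transcript length across genes, which are not independent replicates (Spearman's rho -0.27), from a median of 0.24 in the shortest of 5 equal bins to -0.11 in the longest. Removing each library's GC and length trends, a step added after the data were seen, moved the share of calls that were rises from 47.2% to 32.7% and the median log2 fold change from 0.02 to -0.09.

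**Figure D2:**
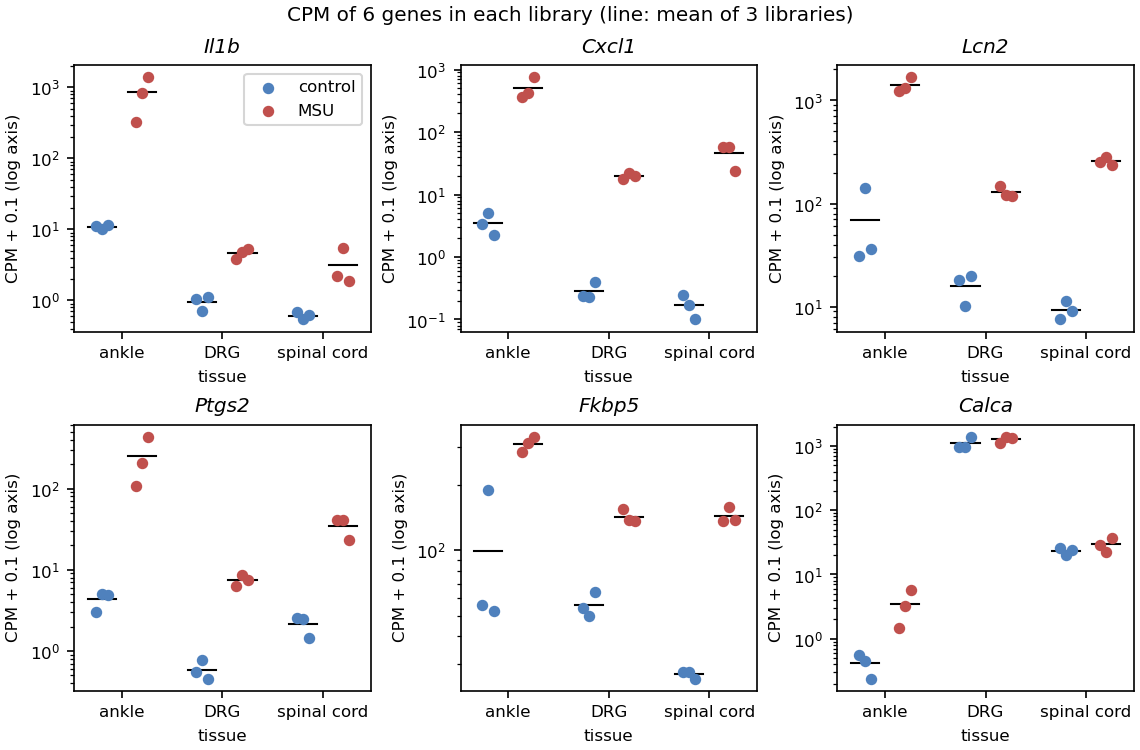
CPM plus 0.1 on a log axis for Il1b, Cxcl1, Lcn2, Ptgs2, Fkbp5 and Calca in each of the 18 libraries, by tissue and group, with a line at each group's mean. Il1b rose from a mean of 10.8 to 850 CPM in the ankle joint and from 0.858 to 4.54 CPM in the DRG.

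In the spinal cord, the comparison asks whether the central end of the pathway responds within 8 h. Glucocorticoid-induced and acute phase transcripts rose, and several endothelial, microglial and oligodendrocyte genes fell. Plin4 (ENSMUSG00000002831), a lipid droplet gene that glucocorticoids induce, rose 40.8-fold, from 6.35 ± 1.45 to 259 ± 15.6 CPM (n = 3, log2 fold change 5.35, SE 0.13, edgeR adjusted p = 9.27e-11). Lcn2 (ENSMUSG00000026822) rose 28.4-fold, from 9.17 ± 1.87 to 257 ± 22.1 CPM (log2 fold change 4.83, SE 0.13, adjusted p = 7.52e-10). Fkbp5 (ENSMUSG00000024222) rose 5.43-fold, from 26.6 ± 1.08 to 145 ± 12.5 CPM (log2 fold change 2.44, SE 0.09, adjusted p = 2.38e-09). Kdr (ENSMUSG00000062960), the endothelial VEGF receptor gene, fell by 2.27 on the log2 scale, from 26.2 ± 6.5 to 5.42 ± 1.24 CPM (SE 0.21, adjusted p = 9.80e-05). In each of these 4 genes the MSU libraries were separated from all 3 controls.

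Of 16 glucocorticoid-induced genes, 15 rose in the spinal cord (16 when adjusted over the list alone, camera adjusted p = 1.99e-25, adjusted p = 0.182 with an estimated correlation). Map3k6 rose 11.4-fold, the transcription factor gene Zbtb16 5.18-fold, and Sgk1, named after its value was seen, was the member not called (log2 fold change 2.51, adjusted p = 0.0786). Of 18 acute phase and glial reactivity genes, 11 rose (13 when adjusted over the list alone, camera adjusted p = 6.61e-14, adjusted p = 0.294 with an estimated correlation). Socs3, the feedback inhibitor of cytokine signalling, rose 14.3-fold, and Gfap had a log2 fold change of 0.94 (827 ± 257 to 1589 ± 714 CPM, adjusted p = 0.315). Of 22 cytokines and NF-kB targets, 15 rose and 1 fell (16 and 1 when adjusted over the list alone, camera adjusted p = 7.47e-14, adjusted p = 0.226 with an estimated correlation). Selp rose 231-fold, Sele 77.7-fold and Icam1 6.85-fold, and the alarmin gene Il33 fell by 0.53, named after its value was seen. Il6 had 109 counts with MSU and 1 in the controls, a ratio of 81.9 (95% counting interval 14.4 to 3263). Of 10 neutrophil chemoattractants and receptors, 6 rose (7 when adjusted over the list alone, camera adjusted p = 1.02e-06, adjusted p = 0.226 with an estimated correlation). Csf3 had 3160 counts with MSU and 3 in the controls, a ratio of 791 (95% counting interval 270 to 3838), and Cxcl1 rose 511-fold, with an adjusted p of 0.00368 in edgeR and 0.0814 in limma-voom (6.24e-21 to 0.0814 over the alternatives). Of 21 immediate early genes, 9 rose and 1 fell (11 and 1 when adjusted over the list alone, camera adjusted p = 1.61e-07, adjusted p = 0.460 with an estimated correlation). Fosl2 rose 4.91-fold and Junb 4.02-fold, while the neuronal gene Arc fell by 0.91, and 2 members fell without spinal cord MSU 1. Fos had a log2 fold change of 0.74 (adjusted p = 0.216), and 1.12 without spinal cord control 3 (adjusted p = 0.0102).

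Of 15 interleukin-1 and inflammasome genes, 6 rose (7 when adjusted over the list alone, camera adjusted p = 8.02e-05, adjusted p = 0.462 with an estimated correlation). Il1rn rose 47.3-fold and the decoy receptor gene Il1r2 14.9-fold. Il1b rose 5.85-fold, from 0.512 ± 0.0707 to 3.09 ± 1.99 CPM (adjusted p = 0.00489, and 0.0982 in the fit of all 18 libraries, 2.34e-10 to 0.0982 over the alternatives). Of 16 mature neutrophil markers, 9 rose (13 when adjusted over the list alone, camera adjusted p = 3.90e-08, adjusted p = 0.460 with an estimated correlation). Of 10 erythroid markers, 0 rose by edgeR (7 at an unadjusted p under 0.05, 6 when adjusted over the list alone, camera adjusted p = 0.000707, adjusted p = 0.481 with an estimated correlation), and 2 rose without spinal cord control 2, 1 without control 3 and 4 without MSU 3. S100a9 had a log2 fold change of 1.63 (adjusted p = 0.128), with 29.4 CPM in spinal cord MSU 3 against 75.5 and 86.4 CPM in MSU 1 and 2, and 1.98 without spinal cord MSU 3 (adjusted p = 8.57e-08). Of 16 monocyte and macrophage markers, 9 rose, or 5 without spinal cord control 1 or control 3 (10 when adjusted over the list alone, camera adjusted p = 1.65e-05, adjusted p = 0.481 with an estimated correlation), including Cd14 at 10.9-fold. Ptgs2 rose 16.7-fold, from 2.05 ± 0.626 to 35.0 ± 10.3 CPM (log2 fold change 4.06, SE 0.31, adjusted p = 0.000191).

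Several resident-cell genes fell in the spinal cord. Of 12 endothelial markers, 5 fell and 1 rose (7 and 1 when adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.584 with an estimated correlation), and 3 fell without spinal cord control 1. The angiopoietin receptor gene Tek fell by 1.83 and the von Willebrand factor gene Vwf by 1.52, while Ly6c1, named after its value was seen, rose by 0.70 on the log2 scale, a call lost without spinal cord control 2, control 3, MSU 1 or MSU 3. Of 14 microglia markers, 5 fell and 2 rose (6 and 3 when adjusted over the list alone, camera adjusted p = 0.127, adjusted p = 0.636 with an estimated correlation), and 3 fell without spinal cord control 2 or MSU 1. P2ry12, the purine receptor of resting microglia, fell by 1.42, from 18.6 ± 0.509 to 6.97 ± 1.96 CPM (SE 0.17, adjusted p = 0.000151), and Gpr34 fell by 2.13. The rises were the complement gene C1qa at 1.65-fold, with an adjusted p of 0.168 in the fit of all 18 libraries (2.01e-11 to 1 over the alternatives), and Selplg (log2 fold change 0.71), named after its value was seen, and 1 of the pair passed without spinal cord control 2. Of 12 oligodendrocyte markers, 3 fell (3 when adjusted over the list alone, camera adjusted p = 0.0447, adjusted p = 0.584 with an estimated correlation), and 6 fell without spinal cord MSU 2 while 2 rose without MSU 3. Opalin, an oligodendrocyte membrane protein gene, fell by 2.29, from 34.4 ± 3.73 to 7.03 ± 1.97 CPM (SE 0.17, adjusted p = 9.01e-06).

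Genes of pain transmission rarely passed the test in the cord. Of 27 spinal pain transmission genes, 1 fell, the purine receptor gene P2rx7 (log2 fold change -0.40, adjusted p = 0.0402, 0.0159 to 1 over the alternatives) (0 by edgeR when adjusted over the list alone, 3 at an unadjusted p under 0.05, camera adjusted p = 0.327, adjusted p = 0.584 with an estimated correlation). That call was lost without any 1 of spinal cord controls 1 to 3, MSU 1 or MSU 2, and 2 genes fell without MSU 3. Tac1 had a log2 fold change of -0.08 (adjusted p = 0.814) and Calca of 0.35 (adjusted p = 0.270), the latter 0.51 without spinal cord MSU 2 (adjusted p = 0.0273). Atf3 rose 3.31-fold (adjusted p = 0.0029).

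The test called 980 spinal cord genes higher and 712 lower with MSU of 17507 tested, of which 402 and 136 changed at least 2-fold, and the groups did not overlap for 27.7% of genes. The number of lower genes was 382, 412 and 444 without spinal cord control 1, 2 or 3, 359 without spinal cord MSU 1, and 365 in the fit of all 18 libraries. That fit put the share of rises among the calls at 70.0%, against 57.9% as reported. Fold changes rose with GC content across genes (Spearman's rho 0.27), from a median of -0.15 in the lowest of 5 equal bins to 0.07 in the highest. With transcript length rho was -0.15, and genes are not independent replicates. After the correction for GC content and gene length 934 genes were higher and 645 lower.

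**Figure D3:**
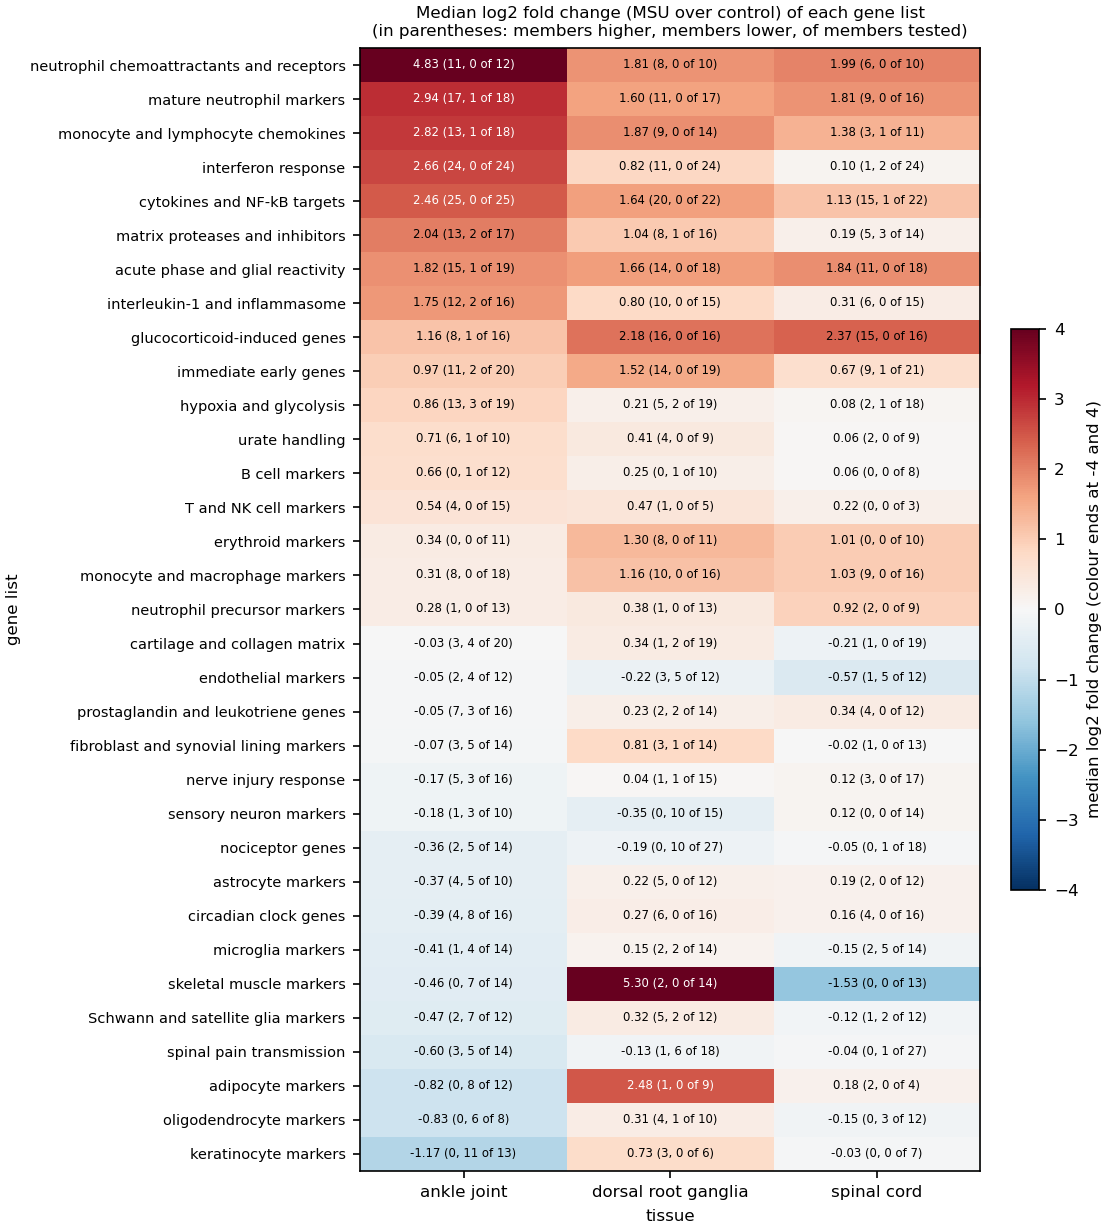
Median log2 fold change (MSU against control, colour from -4 to 4) of 33 gene lists in the 3 tissues, with the number of members higher and lower of those tested in each cell. All 24 tested interferon response genes were higher in the ankle joint, and all 16 glucocorticoid-induced genes in the DRG.

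Calls overlapped between tissues. The column labels share numbers across tissues and do not say whether these mark the same animals. The expected overlaps and Fisher's exact tests take the tissues and the genes as independent, so their p-values do not measure the spread between samples. Fold changes correlated weakly across genes (Spearman's rho 0.20 for ankle and DRG, 0.25 for ankle and spinal cord, 0.26 for DRG and spinal cord). In all 3 tissues 362 genes rose, against 38.4 if the calls were independent, and 110 fell, against 26.4, of 14767 genes tested in each. Of the genes tested in both DRG and spinal cord, 543 rose in both, against 161 by chance (Fisher's exact test, adjusted p = 6.39e-186), and 215 fell in both, against 131 (adjusted p = 4.96e-15). Ankle joint and DRG shared 1083 rises, against 623 by chance (Fisher's exact test, adjusted p = 4.62e-107), and 946 falls, against 626 (adjusted p = 2.49e-53). Ankle joint and spinal cord shared 517 rises, against 213 by chance (Fisher's exact test, adjusted p = 4.94e-109), and 259 falls, against 139 (adjusted p = 1.14e-27). Opposite calls were fewer than by chance but occurred. Between ankle and DRG 472 genes rose in the ankle and fell in the DRG, against 645, and 327 did the reverse, against 605. The values were 70, against 143, and 125, against 206, for ankle and spinal cord. They were 38, against 114, and 76, against 185, for DRG and spinal cord. Among the genes called in all 3 with the smallest p-values were Il1r1, with log2 fold changes of 1.82, 1.68 and 1.68 in ankle, DRG and spinal cord, Nfkbia with 2.63, 2.06 and 1.91, and the interleukin-17 receptor gene Il17ra with 1.77, 1.88 and 1.34. The oncostatin M receptor gene Osmr had 1.99, 1.13 and 2.41, and Slc2a1, the blood-brain barrier glucose transporter gene, 1.49, 0.78 and 0.99.

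The size of the response differed between tissues for many genes, tested as an interaction in a fit of all 18 libraries and 20757 genes. It differed for 6735 genes between ankle and DRG, 5542 between ankle and spinal cord, and 2815 between DRG and spinal cord, the last being 1847 without DRG MSU 3 and 1719 after the correction for GC content and gene length. The log2 fold change was higher in the ankle for 2972 and in the DRG for 3763. It was higher in the ankle for 1899 and in the cord for 3643, and in the DRG for 646 and in the cord for 2169. The median log2 fold change in this fit was -0.13 in the ankle, -0.03 in the DRG and 0.003 in the cord. That offset runs the same way as these excesses, and the fit uses 1 dispersion per gene for the 3 tissues. The interferon response was higher in the ankle than in the DRG for 22 of 24 genes (camera adjusted p = 4.42e-12, adjusted p = 0.341 with an estimated correlation). It was higher in the ankle than in the cord for 23 of 24 (camera adjusted p = 1.65e-19, adjusted p = 0.194 with an estimated correlation). Nos2, the inducible nitric oxide synthase gene, responded more in the ankle than in the DRG by 5.76 on the log2 scale (SE 0.52, adjusted p = 3.25e-07) and than in the cord by 7.27 (SE 0.34, adjusted p = 1.31e-10). Plin4 went the other way, with a log2 difference of -6.81 between ankle and DRG (SE 0.31, adjusted p = 1.47e-09) and -6.61 between ankle and cord (SE 0.31, adjusted p = 1.41e-09).

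**Figure D4:**
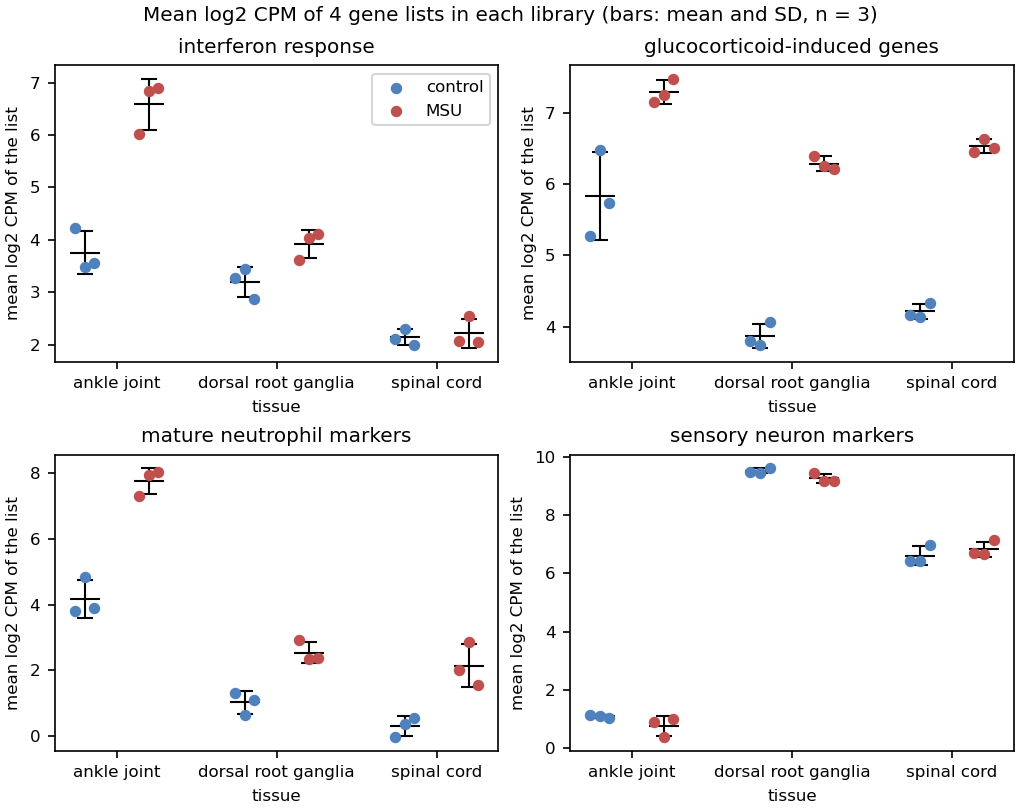
Mean log2 CPM of interferon response, glucocorticoid-induced, mature neutrophil marker and sensory neuron marker genes in each library of the 3 tissues, with bars for the mean and SD of 3 libraries per group. The interferon response separates MSU from control in the ankle joint, where all 24 tested genes rose.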

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

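The differences listed first were picked out because the response differed between 2 tissues by a test of the difference itself. The glucocorticoid, neutrophil and sensory neuron patterns weighed after them were not picked by that rule. The gene tests were planned; the list tests between tissues, the weighing of explanations and the splits of the samples were chosen only after the results were seen.

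In 10 lists, at least 0.5 of the tested members differed between ankle and DRG in the same direction, and lists that met this rule in the other pairs follow. The median log2 difference (ankle minus DRG) was 0.96 for cytokines and NF-kB targets, 1.77 for the interferon response, 0.53 for hypoxia and glycolysis and 1.96 for mature neutrophil markers. It was -0.68 for clock genes, -5.63 for skeletal muscle markers, -3.35 for adipocyte markers, -0.82 for microglia markers, -1.43 for oligodendrocyte markers and -0.79 for Schwann and satellite glia markers. Between ankle and spinal cord it was 2.54 for the interferon response, -0.47 for clock genes and -0.53 for Schwann and satellite glia markers, and between DRG and spinal cord 7.04 for skeletal muscle markers, with all 14 higher in the DRG (camera adjusted p = 6.23e-13, adjusted p = 0.686 with an estimated correlation). Camera on the difference missed the threshold for microglia markers (adjusted p = 0.0570), for Schwann markers against the DRG (0.0750) and the spinal cord (0.451), and for clock genes against the spinal cord (0.167). With an estimated correlation no list passed in any pair, with a smallest adjusted p of 0.341 for ankle and DRG, 0.194 for ankle and spinal cord and 0.686 for DRG and spinal cord. DRG MSU 1 carried much of the muscle and adipocyte differences: its mean log2 CPM of adipocyte markers was 3.65, against 0.81 and 0.54 in DRG MSU 2 and 3 and -0.55 to 0.54 in the controls. Without it the median DRG log2 fold change went from 2.48 to 0.66 for adipocyte markers and from 5.30 to 3.31 for skeletal muscle markers.

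Among single genes, the log2 difference (ankle minus DRG) was positive for the chemokine gene Ccl3 (6.55), Nos2 (5.76), Il6 (4.98), Nlrp3 (3.98) and Il1b (3.85). These genes rose more in the ankle. It was negative for the muscle genes Lmod2 (-6.79) and Mb (-7.06), for Plin4 (-6.81), for Odf3l2 (-7.49), a sperm tail protein gene with 3 counts in the DRG controls (MSU to control ratio 217, 95% counting interval 73.9 to 1056), and for Cyp2e1 (-7.63), whose log2 fold change in this fit was -4.81 in the ankle and 2.81 in the DRG. Without DRG control 2 the edgeR adjusted p of Ccl3 rose from 0.0190 to 0.280. With limma-voom the adjusted p was 0.136 for Ccl3, 0.11 for Nlrp3, 0.128 for Il1b and 0.0681 for Mb (3.54e-08 to 0.280, 1.17e-09 to 0.11, 3.43e-07 to 0.128 and 1.82e-06 to 0.0681 over the alternatives). For ankle minus spinal cord the difference was positive for the chemokine genes Ccl4 (9.43), Ccl3 (7.81) and Cxcl5 (6.65), for Nos2 (7.27) and for Adamts4 (5.03). It was negative for the selectin genes Sele (-4.21) and Selp (-4.56), which rose more in the cord, and for Wnt2 (-3.90), Inmt (-5.29) and Plin4 (-6.61), which fell in the ankle. The edgeR adjusted p of Ccl4, which had 7 and 3 counts in control and MSU cords, rose from 0.0118 to 0.103 without spinal cord control 2 and 0.0629 without control 3. With limma-voom it was 0.0930 for Ccl4, 0.0566 for Ccl3 and 0.0501 for Wnt2 (8.91e-15 to 0.103, 2.34e-11 to 0.0566 and 0.000323 to 0.0501 over the alternatives).

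For DRG minus spinal cord the difference was positive for Odf3l2 (7.38), the muscle genes Myl1 (7.12) and Mylpf (6.60), the amino acid transporter gene Slc38a5 (3.22) and Adamts4 (2.79). It was negative for the aggrecan gene Acan (-2.29), whose log2 fold change was -2.04 in the DRG and 0.25 in the cord, for the adenosine deaminase gene Ada (-1.86), the urokinase receptor gene Plaur (-3.74), the transporter gene Slc10a6 (-4.02) and the protease inhibitor gene Serpina3f (-4.03). The edgeR adjusted p of Acan was 0.0511 and 0.0539 without DRG MSU 2 or 3, that of Slc10a6 0.0668 and that of Serpina3f 0.0532 without spinal cord control 1. That of Odf3l2 (0.0307) was 0.0715 and 0.0692 without DRG control 1 or 3, 0.0666, 0.0531 and 0.119 without spinal cord control 1, 2 or 3, 0.0513 without spinal cord MSU 2, and 0.0759 with no count filter (0.000142 to 0.119 over the alternatives). Odf3l2 had 3 counts in the DRG controls and 558 with MSU (ratio 217, 95% counting interval 73.9 to 1056), and Serpina3f had 1 count in the control cords and 196 with MSU (ratio 147, 26.1 to 5844), so their fitted differences here depend on the prior count. With limma-voom 6 of these 10 calls ended, at an adjusted p of 0.106 for Odf3l2, 0.0543 for Myl1, 0.0573 for Mylpf, 0.235 for Acan, 0.104 for Plaur and 0.128 for Slc10a6. DESeq2 gave no adjusted p for the differences of Myl1 and Mylpf here or of Lmod2 between ankle and DRG.

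Glucocorticoid-induced genes rose in DRG and spinal cord, from a summed 599 ± 56.8 to 2803 ± 198 CPM and from 758 ± 107 to 3103 ± 301 CPM. Neutrophils carrying these transcripts are argued against, because the summed rise without Mt1 was at least 5.87 times that of the mature neutrophil markers in each of the 6 MSU libraries. A GC or length trend is argued against as well, with 16 members in the DRG and 15 in the spinal cord higher after the correction. A difference in collection time stays open: 7 clock output genes had a median log2 fold change of 0.30 in the DRG and 0.14 in the spinal cord, and the list of 16 clock genes moved upward in both (camera adjusted p = 0.0407 and 0.00800, adjusted p = 0.314 and 0.481 with an estimated correlation). A systemic stress or steroid response to the inflamed joint, or to handling, may account for the pattern and was not tested.

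Mature neutrophil markers rose in DRG and spinal cord, from a summed 133 ± 35.5 to 314 ± 130 CPM and from 95.2 ± 7.63 to 215 ± 76.2 CPM. The DRG sum was 464 CPM in DRG MSU 1 against 232 and 247 CPM in DRG MSU 2 and 3, and 168, 97.4 and 133 CPM in the controls. S100a8 and S100a9, neither called by edgeR in the DRG, made up 61.2 and 123 CPM of the DRG MSU mean. Reads carried over from the ankle MSU libraries are argued against for S100a9. The level of Mmp3 allowed 2.14% of its increase in mean CPM in the DRG and 0.214% in the spinal cord. S100a9 itself was not called by edgeR in either tissue, and the other markers were not tested in this way. More blood left in the tissue stays open. The smallest gap by which the median log2 rise of neutrophil markers exceeded that of erythroid markers, over the 3 MSU libraries, was 0.0749 in the DRG and 0.727 in the spinal cord, and a higher share of neutrophils in the blood, not tested here, could widen it. Neutrophils held in vessels or entering the tissue may add to the pattern, and these samples cannot separate the sources. Some markers hardly moved, while 11 of 17 rose in the DRG. Mmp9 went from 12.6 ± 2.15 to 15.2 ± 6.21 CPM in the DRG and from 20.5 ± 2.03 to 20.9 ± 3.80 CPM in the spinal cord. Retnlg, named after its values were seen, stood at 7.70 and 8.39 CPM in DRG MSU 2 and 3, within the 4.74 to 9.97 CPM of the controls. Whether neutrophils held the marker transcripts was not tested.

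Of 41 tested sensory neuron and nociceptor genes, 19 fell in the DRG. After the GC and length correction 25 were lower. That correction also moved the DRG median log2 fold change from 0.02 to -0.09 and all lower calls from 3177 to 3905. The count of 25 therefore cannot decide on a GC or length trend. Without DRG MSU 1, 100% of the 19 were still lower, which argues against dilution by the muscle RNA of that library. Summed muscle markers in DRG MSU 2 and 3 (2174 and 2138 CPM) still stood above the controls (409, 260 and 90.2 CPM), so that fit did not remove the muscle difference. The spread of the changes (Cochran's Q over degrees of freedom 7.65) argues against a common fall of all 41 genes, with the genes taken as independent. It cannot exclude a lower share of neurons as the only cause. Members that other cells also express would vary under that cause too, and Pvalb is on the skeletal muscle list as well. A lower share combined with changes in single genes would give such a spread too and stays open. While 10 members lay above 0, no rise was called, and the weighted mean log2 fold change was -0.305. A regulated change in part of the neuronal transcripts, a response to handling and a shift among neuron types may each contribute, and none was tested.

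In the other splits of each tissue's 6 libraries into groups of 3 (10 splits, the real one included), 1 split, the real one, reached the reported counts, and the highest of the others was 0 genes by edgeR (highest number at an unadjusted p under 0.05: 451 in the ankle, 545 in the DRG and 1173 in the spinal cord). The real values were 3823 and 3833, 2844 and 3177, and 980 and 712 genes, and 10 splits are too few for a share under 0.05. Each other split also placed control and MSU libraries in both groups, so the MSU effect added to the spread within groups. The 0 calls of those splits therefore cannot decide on chance. For the differences between tissues, 1 of 40 splits, the real one, reached the reported 6735, 5542 and 2815 genes. The highest others were 3009, 3643 and 977, each from a split in which 1 tissue kept its own labels. Chance is excluded at 0.025 only as a random assignment of the libraries in both tissues: exchanging labels removes the MSU effect itself, so these splits do not test equal responses in 2 tissues.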

How the results depend on the processing

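The correction for GC content and gene length was chosen after the data were seen; the other settings here were planned. The counts of higher and lower genes stayed within 1.5 times the reported value under RLE and upper quartile size factors, both count filters, DESeq2 and limma-voom in the 3 tissues. The test against a 1.5-fold change called 1504 higher and 1526 lower genes in the ankle, 479 and 105 in the DRG, and 287 and 67 in the spinal cord. A log2 fold change of at least 1 left 1504 and 1808, 827 and 147, and 402 and 136. Both settings are stricter by construction.

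Without 1 library the ankle counts ranged from 3164 to 3503 higher and 3068 to 3534 lower, the DRG counts from 1916 to 3354 and 2135 to 3688, and the spinal cord counts from 654 to 1146 and 359 to 724. The number of lower genes in the spinal cord was 382 without spinal cord control 1, 412 without control 2, 444 without control 3 and 359 without MSU 1, against 712 as reported, and 365 in the fit of all 18 libraries; the cause was not tested. The median log2 fold change over all genes moved by more than 0.1 toward lower values in the ankle with upper quartile factors (-0.12) and the fit of all libraries (-0.13), against -0.02 as reported, and in the DRG with the GC and length correction (-0.09 against 0.02).

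Genes whose response differed between DRG and spinal cord numbered 2815 as reported and 1719 after the GC and length correction. Without 1 library they ranged from 1847 (without DRG MSU 3) to 3216 (without DRG MSU 1), a range that does not cover the other tools. The cause was not tested. The other pairs of tissues stayed within 1.5 times, at 5887 to 6800 for ankle and DRG and 4818 to 5690 for ankle and spinal cord without 1 library, and at 5808 (no count filter) to 7195 (DESeq2) and 4744 (no count filter) to 5938 (DESeq2) over all settings. Overlaps at an adjusted p under 0.01, stricter by construction, were 535 higher and 424 lower for ankle and DRG, 290 and 89 for ankle and spinal cord, and 298 and 58 for DRG and spinal cord.

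Of 33 gene lists, camera called 17 in the ankle, 18 in the DRG and 16 in the spinal cord with a correlation of 0.01, and 0, 0 and 0 with an estimated correlation, where the smallest adjusted p was 0.366 in the ankle, 0.0585 in the DRG and 0.182 in the spinal cord. fry, which asks whether a list moved at all and not whether it moved more than other genes, called 20, 19 and 11. Of these, 14, 16 and 9 were also called by camera. The camera calls therefore rest on the fixed setting, and fry shared a part of them. The size of the correlation alone does not account for the loss. In the DRG, cytokines and NF-kB targets had an estimated correlation of -0.0105, below 0.01. Their unadjusted camera p was still 0.00177 with the estimate, against 1.69e-11 with the fixed value.

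Of 172 named ankle genes, leaving out 1 library ended the call of 5 and added that of 7, and of 168 named in the DRG it ended 21 and added 12. Of 160 in the spinal cord it ended 18 and added 23. In the ankle, Atf3 changed sign: its log2 fold change was -0.03 as reported, ranged from -0.29 (without ankle control 1) to 0.55 (without ankle control 2, edgeR adjusted p = 0.0368), and the cause was not tested.

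Replicate numbers were tried as a block, though control and MSU libraries of the same number were little correlated (0.23, 0.15 and -0.06 in the ankle, 0.14, 0.05 and 0.02 in the DRG, 0.17, 0.09 and -0.13 in the spinal cord). These numbers come from the sample titles and differ from those of the column labels. Pairs sharing a column number were ankle control 3 and MSU 2 (0.26), DRG control 3 and MSU 3 (0.02), and spinal cord control 3 and MSU 2 (0.16). The block gave 3709 and 3759 calls in the ankle, 2464 and 2674 in the DRG, and 976 and 693 in the spinal cord. Depth limits the genes near the floor, where 3 counts equalled 0.0773 to 0.258 CPM. Simulated 1.5-fold changes were recovered for 7.46% of genes in the ankle, where the biological coefficient of variation was 0.209, against 0.154 in the DRG and 0.11 in the spinal cord.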

Other observations

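The values here were read after the data were seen, and no explanation is offered for them. Of 10 tested genes of urate handling in the ankle, 6 rose and 1 fell (6 and 1 when adjusted over the list alone, camera adjusted p = 0.0837, adjusted p = 0.366 with an estimated correlation). Of 9 tested in the DRG, 4 rose (6 and 1 lower when adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.520 with an estimated correlation), or 7 without DRG MSU 1 and 2 after the GC and length correction, and 1 fell without DRG control 3. Of 9 in the spinal cord, 2 rose, Xdh and Ada (2 when adjusted over the list alone, camera adjusted p = 0.145, adjusted p = 0.481 with an estimated correlation). Xdh, which encodes the xanthine oxidoreductase that makes urate, rose 4.26-fold in the ankle, 7.72-fold in the DRG and 3.77-fold in the spinal cord, with all 3 MSU libraries above all 3 controls in each tissue. Slc2a9, a urate transporter gene, fell by 1.04 on the log2 scale in the ankle. Ada, which turns adenosine into inosine, rose 5.12-fold in the spinal cord.

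Of 16 clock genes, 4 rose and 8 fell in the ankle (4 and 9 when adjusted over the list alone, camera adjusted p = 0.251, adjusted p = 0.578 with an estimated correlation), and 2 rose without ankle control 3, ankle MSU 1 or ankle MSU 3. The clock output genes Hlf and Tef fell by 1.86 and 1.02 on the log2 scale, and Nr1d1, a clock repressor gene, by 1.52. In the DRG 6 rose (6 and 1 lower when adjusted over the list alone, camera adjusted p = 0.0407, adjusted p = 0.314 with an estimated correlation), and 1 fell without DRG MSU 1. In the spinal cord 4 rose (5 when adjusted over the list alone, camera adjusted p = 0.00800, adjusted p = 0.481 with an estimated correlation). Per1, a clock gene that glucocorticoids induce, rose 3.16-fold in the DRG and 1.83-fold in the spinal cord.

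Single libraries stood apart from their group. In ankle control 2 the glucocorticoid-induced gene Zbtb16 stood at 102 CPM against 19.5 and 13.9 in the other controls, Tsc22d3 at 446 against 95.5 and 158, and S100a8 at 181 against 47.1 and 55.7. In spinal cord MSU 3 the haemoglobin gene Hbb-bs stood at 85.7 CPM against 134 and 148 in the other MSU libraries. The mean log2 CPM of nociceptor genes was 1.60 in spinal cord control 3 and 2.10 in MSU 3, against 0.666 to 0.997 in the other cord libraries.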
